A study of Mus musculus with 22 samples.

How the data were processed

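Single-cell RNA sequencing by CEL-Seq2, a plate-based method that counts the 3' ends of transcripts with unique molecular identifiers, was done on cells sorted from the terminal ileum of BALB/c mice, 21 days after they received an allogeneic transplant of hematopoietic cells. Per the labels' protocols, recipients were irradiated with 2 doses of 5 Gy and given 5000000 bone marrow cells of C57BL/6 donors, with 400000 donor T cells in the acute graft-versus-host disease (aGVHD) group and none in the control group. Cells were sorted as CD45+H2kb+CD11b+Ly6G+, a gate for donor-derived neutrophils. Each of the 22 libraries came as 1 table of genes by 192 barcodes. The groups were taken from the sample descriptions, giving 10 control and 12 aGVHD libraries. The titles fall into 2 sets, the dated set, whose titles carry a date-like number (6 control and 8 aGVHD libraries), and the G1 set, whose titles carry G1 (4 and 4). The set entered the models as a covariate. No label ties a library to a mouse, so p-values measure only the spread between libraries, which may be technical.

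Per the submitters' processing notes, bcl2fastq 2.17.1.14 and BWA 0.6.2-r126 were used; the genome build is not given in the sources used here, and no coordinates are reported. The deposited values are estimated counts of transcripts per gene and barcode, not normalised for depth. Each of the 1419098 values above 0 equals the number of transcripts expected from a whole number of identifiers drawn from 4096, with no value failing this at a tolerance of 1e-06. They were rounded to whole transcripts. The tables named 23091 genes together.

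Of the 4224 barcodes, 1383 with at least 500 transcripts were kept as cells. In each library 96 of the barcodes were taken to have received cells, as read from the totals and not from a label. The other 96, which held 1.42% to 15.99% of a library's transcripts and 2 of the kept cells in all, were used as a measure of background. Unnamed gene models took a mean of 52.0% of the transcripts in kept cells (range 31.9% to 78.6% over libraries), and Gm10800 alone took 34.5%. They count toward the minimum of 500. No doublet caller was run; a quality filter, tried as an alternative, left out cells with over 4 times their library's median total or with over 2% of transcripts from Kcnq1ot1.

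Cells were clustered on Pearson residuals (overdispersion 100) of the 200 most variable genes among the marker genes and gene lists fixed before the data were examined, using 12 principal components, 15 neighbours and the Leiden algorithm at resolution 1.0 (igraph 0.11.9, leidenalg 0.10.2). This gene set was chosen after 3 kinds of clustering had been looked at, by cluster content and mixing of the title sets and before any test between groups; the other 2 were run as alternatives. A cluster was named for a cell class if at least 3 of its markers were raised at least 1.5-fold over all other cells with at least 10 transcripts, if more were raised than for any other class, and if no other class had more markers among its 10 leading genes. A cluster with a median total below 0.33 of its library's median and no marker among those 10 stayed unnamed. These thresholds were set after seeing the data. They left 573 cells unnamed, 164 of 358 in the control group and 409 of 1025 in the aGVHD group.

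Transcripts were summed per library, over all kept cells or over neutrophil-like cells in libraries with at least 10 of them. The count model planned before the data were examined was not used, because the column check applied to the tables could not read their tab-separated cells as counts, and their unit was entered there as other. Alternatives with a second count model were not run for the same reason. The sums were tested instead with limma 3.58.1 (R 4.3.3): log2 CPM (transcripts scaled to the same library total) with voom precision weights, trimmed-mean scaling (trim 0.3 of ratios and 0.05 of levels), a low-count filter of at least 10 transcripts at the median library size and 15 in total, and Benjamini-Hochberg adjustment at 0.05. Cells of both Lcn2 statuses were compared with the library as a block, after thinning each cell to 500 transcripts, in libraries with at least 5 cells of each status. Shares of cells were compared by two-sided permutation of group labels within title sets, with 100000 resamples, or exactly where a group had fewer than 10 libraries (Python 3.11.15, scipy 1.17.1). Gene lists fixed before the data were examined were tested with camera at a preset correlation of 0.01 and at an estimated one, and with fry. On simulated sums with 200 changed genes, the test recovered 41% of log2 changes of 1 and 100% of changes of 2 over all gated cells (2382 genes), 30% and 95% over neutrophil-like cells (1221 genes), and 37% and 88% for Lcn2 status (290 genes). The simulation used a dispersion of 0.2 in each comparison. These rates hold for that setting only, and not for genes that vary more between libraries.

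Genes named from the comparisons followed a rule fixed before the data were examined: Lcn2, and the 10 highest and 10 lowest log2 fold changes (8 and 8 for Lcn2 status) with adjusted p under 0.05, a mean of at least 50 CPM and, between groups, the same sign in both title sets, leaving out unnamed gene models, immunoglobulin and T cell receptor segments, ribosomal and mitochondrial genes. From the fixed lists, up to 4 members with the smallest p were eligible in neutrophil-like cells. Applying the rule to all gated cells as well was decided after seeing the data. Alternatives covered scaling, the low-count and cell filters, the covariate, title sets alone, 4 sums, a block of title numbers, clustering, thinning, and each library left out.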

Results

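The data compared neutrophils of the terminal ileum between mice with aGVHD and transplanted mice without donor T cells, with lipocalin-2 (Lcn2), an iron-siderophore-binding protein of neutrophil granules, as the gene named in the study's title. Totals per library ran from 45607 to 360054 transcripts. Control libraries held 11 to 60 kept cells and aGVHD libraries 74 to 95, so control sums were the shallower side of the comparisons between groups. Per kept cell, the median depth of a library averaged 2616 transcripts in control and 2314 in aGVHD libraries. Control replicates 5, 9 and 10 held 12, 12 and 11 cells.

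Of the 1383 cells, 651 fell into 6 clusters carrying neutrophil markers, 123 from control and 528 from aGVHD libraries. Further cells were macrophage/monocyte-like (100 cells), B or plasma cell-like (30) and epithelial-like (29). Neutrophil-like cells made up 29.9% ± 12.3 (SD, n = 10) of kept cells per control library and 51.4% ± 19.4 (SD, n = 12) per aGVHD library, a difference of 21.5 percentage points (permutation test, two-sided p = 0.00478). The macrophage/monocyte-like share was 14.1% ± 4.86 (SD, n = 10) in control and 5.34% ± 2.40 (SD, n = 12) in aGVHD libraries (p = 1e-05, the smallest value 100000 permutations can give, and 4e-05 after adjustment over 4 classes). These cells numbered 45 of 358 kept cells in control and 55 of 1025 in aGVHD libraries. The lower share in aGVHD therefore does not mean fewer such cells. Epithelial-like cells averaged 3.93% and 1.12%, B or plasma cell-like cells 1.86% and 2.05%, and unnamed cells 50.1% and 40.1% (adjusted p = 0.198, 0.925 and 0.198, permutation tests). The neutrophil-like difference was 23.3 points within the dated set (exact permutation p = 0.0276) and 16.4 points within the G1 set (exact permutation p = 0.171), and 15.4 points over libraries of at least 20 cells (exact permutation p = 0.0920). All these shares are of sorted cells and depend on the gate. They also depend on the minimum of transcripts per cell, and a larger share of any class lowers the others. Macrophage/monocyte-like cells were deeper than neutrophil-like cells (medians given below), so the minimum may favour them. At a minimum of 250 and 1000 transcripts the neutrophil-like difference was 15.9 and 21.6 points (permutation p = 0.0239 and 0.0039). Whether the number of kept cells accounts for either difference is not settled.

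Lcn2 was detected in more neutrophil-like cells of aGVHD libraries. After thinning to 500 transcripts per cell, the share with at least 1 Lcn2 transcript was 2.55% ± 4.30 (SD, n = 10) in control and 21.1% ± 16.4 (SD, n = 12) in aGVHD libraries, 18.6 percentage points higher (permutation test, two-sided p = 0.0015). Pooled over libraries these were 6 of 123 cells (4.88%, exact 95% interval 1.81% to 10.3%) and 123 of 528 cells (23.3%, 19.8% to 27.1%), intervals that cover counting error only. In macrophage/monocyte-like, B or plasma cell-like and epithelial-like cells, taken as background, Lcn2 was found in 0 of 71 control cells and in 5 of 88 aGVHD cells (5.68%, exact 95% interval 1.87% to 12.8%). The count of 0 allows up to 3 counts, or 4.23%, and its exact 95% interval reaches 5.06%. The control share was therefore not separable from background. Median depth before thinning was 2270 and 2310 transcripts in control and aGVHD neutrophil-like cells, 5227 and 7456 in macrophage/monocyte-like, 13165 and 14175 in epithelial-like and 1519 and 1261 in B or plasma cell-like cells. Lcn2 in control neutrophil-like cells was at 470 CPM (transcripts scaled to the same library total) of named genes in the dated set and 148 in the G1 set, against 316 and 261 in the barcodes taken as unused in the same libraries. Within the dated set the difference was 14.4 points (exact permutation p = 0.0813) and within the G1 set 26.1 points (exact permutation p = 0.0286). Without thinning it was 20.1 points (41.6% against 21.5%, permutation p = 0.0943), and at 1000 transcripts per cell 12.4 points (permutation p = 0.287), both no longer past 0.05. Nor did it pass over libraries with at least 10 neutrophil-like cells (16.01 points, 5 control libraries, exact permutation p = 0.0521); the other 5 control libraries held 1 to 8 such cells and each counted as 0%. Control replicate 9 held 1 neutrophil-like cell, which counted as 100% in these 2 settings; without that library the differences were 28.9 points (exact permutation p = 0.00507) and 21.7 points (exact permutation p = 0.00769). The difference was 12.2 points over all gated cells (p = 0.0155), 8.34 points for at least 2 Lcn2 transcripts (p = 0.00874) and 12.1 points without cluster 9, described below (p = 0.00231, permutation tests).

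**Figure D1:**
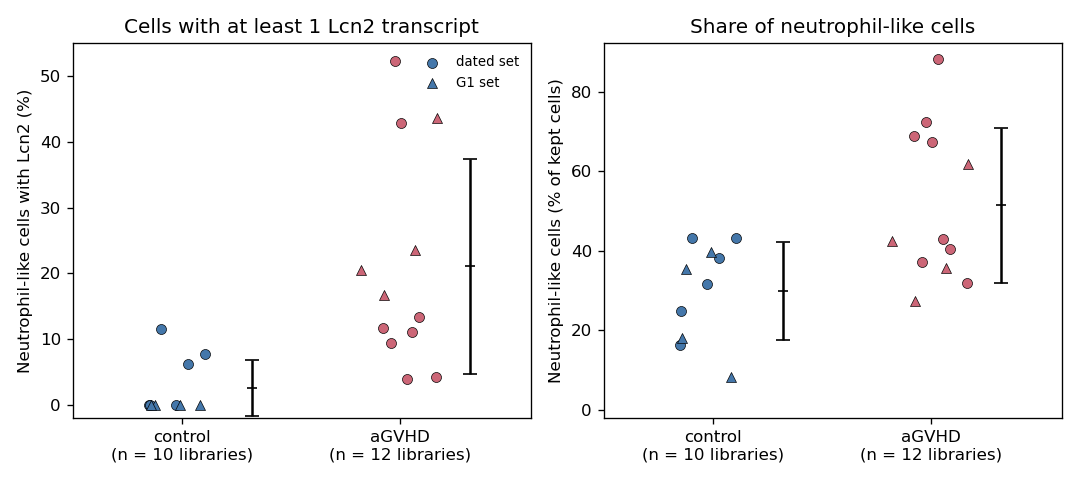
Left, percent of neutrophil-like cells with at least 1 Lcn2 transcript after thinning to 500 transcripts; right, percent of kept cells that were neutrophil-like. Each point is a library (circles the dated set, triangles the G1 set), bars give the mean and SD; the Lcn2 share reached 11.5% in control libraries and ran from 4% to 52.4% in aGVHD libraries.

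The Lcn2 level summed over neutrophil-like cells did not pass the test in the fit over 17 libraries. It was 238 ± 184 CPM (SD, n = 5) in control and 1172 ± 1548 (SD, n = 12) in aGVHD libraries, a log2 fold change of 1.71 (SE 0.98, limma adjusted p = 0.684), and lay above the control mean in 7 of 12 aGVHD libraries. The highest levels were 4577 CPM in aGVHD replicate 7 and 3931 in aGVHD replicate 6. The log2 fold change was 0.62 within the dated set (SE 1.24, limma adjusted p = 0.942) and 3.44 within the G1 set (SE 1.47, limma adjusted p = 0.641). It passed when the libraries were summed to 4 (2.98, limma adjusted p = 5.42e-05), 1 sum per group and title set. Such sums hide the spread between libraries, so that p does not measure it. Of 1787 Lcn2 transcripts in dated aGVHD neutrophil-like cells, 1051 came from replicate 7 and 612 from replicate 6. With title numbers as a replicate block over 6 libraries, Lcn2 passed as well (3.50, SE 0.48, limma adjusted p = 0.00513). Without the block those libraries gave 2.20 (limma adjusted p = 0.741).

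In neutrophil-like cells, 1 of 1221 genes differed between groups at limma's adjusted p under 0.05. Rgs1, a regulator of G protein signalling downstream of chemokine receptors, was lower in aGVHD, at 57.3 ± 50.5 CPM (SD, n = 12) against 265 ± 140 (SD, n = 5), a log2 fold change of -2.04 (SE 0.37, limma adjusted p = 0.0205), and lay below the control mean in 12 of 12 aGVHD libraries. At an unadjusted p under 0.05 there were 104 genes. These fits rest on 17 libraries, 5 of them control. Neutrophil-like cells of aGVHD and control libraries came from the same 6 clusters in different numbers: cluster 9, led by the granule genes Ngp, Ltf and Camp, held 86 of 528 aGVHD and 2 of 123 control cells. Rgs1 rested on 56 transcripts in control and 76 in aGVHD libraries. It no longer passed in several alternatives, among them cells of at least 1000 transcripts, and each title set alone. Its call also ended in 7 of 17 cases with 1 library left out.

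By the fixed gene lists, S100 alarmins and related secreted proteins stood higher in aGVHD neutrophil-like cells than other genes (9 tested, camera adjusted p = 6.28e-05 at the preset correlation), as did specific granule genes (5 tested, adjusted p = 0.00448). Neither call held with an estimated correlation (adjusted p = 0.761 and adjusted p = 0.806), and fry gave an adjusted p of 0.468 for each. Without cluster 9, which held 74.4% of S100a8 and 66.7% of S100a9 transcripts of aGVHD neutrophil-like cells, the alarmins no longer passed (camera adjusted p = 0.0973) and specific granule genes did (0.00612). No member of either list passed over all genes; adjusted over the list alone, 0 alarmins and 1 specific granule gene passed. S100a8, a calcium-binding alarmin subunit, had a log2 fold change of 1.02 (SE 0.38, limma adjusted p = 0.479), its partner S100a9 0.75, the cystatin-like Stfa2 0.83 and Wfdc17 1.22. Stfa2 has near-identical neighbours and its counts are uncertain. Among specific granule genes, haptoglobin (Hp) had 1.41 and the chitinase-like Chil3 and Chil1 had 3.99 and 1.67, with limma adjusted p of 0.445, 0.515 and 0.576. With 1 library left out, Chil1 ran from 1.40 to 2.28.

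Other lists did not pass camera at the preset correlation. Of 14 chemotaxis receptor genes 0 passed over all genes; adjusted over the list alone, 1 was higher and 2 lower: the formyl peptide receptor Fpr2 (log2 fold change 0.72) and the integrin subunits Itga4 (-1.42) and Itgb2 (-0.66), with list adjusted p = 0.712 by camera. Immunoregulatory genes (14 tested, camera adjusted p = 0.712) had a median log2 fold change of 0.03, and the cytokine signalling inhibitor Socs3 had 1.42 (SE 0.51, limma adjusted p = 0.449; 0.61 without control replicate 3). Proinflammatory cytokines (12 tested, adjusted p = 0.714) had a median of -0.11. NF-kB targets (14 tested, adjusted p = 0.128) had a median of -0.30. Interferon response genes (22 tested, adjusted p = 0.123) had a median of 0.22. Antigen presentation genes (11 tested, adjusted p = 0.712) had a median of -0.09. Late maturation genes (15 tested, adjusted p = 0.712) had a median of 0.02, with the resistin-like Retnlg at 2.06 (SE 0.79, limma adjusted p = 0.483). With 1 library left out, Retnlg ran from 1.63 to 2.67.

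Over all gated cells, 124 of 2382 genes differed at limma's adjusted p under 0.05, 61 higher and 63 lower in aGVHD. Of the neutrophil markers fixed in advance, 17 were tested, 17 had a positive log2 fold change and 7 passed. The neutrophil-like share of the same cells was higher as well (51.4% against 29.9%), and none of the genes named here as higher passed within neutrophil-like cells. Over all gated cells, S100a8 had a log2 fold change of 2.01 (SE 0.42, limma adjusted p = 0.0127), from 919.6 ± 554 CPM (SD, n = 10) to 4608 ± 4374 (SD, n = 12), and S100a9 one of 1.53. Chil3 (4.63), Chil1 (1.84), Hp (1.80), Wfdc17 (1.68) and Stfa2 (1.41) rose with them, as did the formyl peptide receptors Fpr1 (1.44) and Fpr2 (1.32) and the myeloid receptor Tarm1 (1.96). Lcn2 had 2.39 (SE 0.83, limma adjusted p = 0.0859), from 46.9 ± 47.5 to 612 ± 850. It passed in some alternatives, among them the G1 set alone (3.59, SE 0.67, limma adjusted p = 0.0241) and without aGVHD replicate 10 (2.59, limma adjusted p = 0.0473). Leaving out 1 library ended the call of Tarm1 in 1 case (control replicate 1, 1.77), of Chil3 in 3 (control replicates 1 and 8, aGVHD replicate 3), of Fpr1 in 4 (control replicates 1, 3, 4 and 8) and of Wfdc17 in 7 of 22 cases (1.54 to 1.65).

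Genes lower in aGVHD over all gated cells included the ileal bile acid-binding protein Fabp6 (-4.83, SE 1.31, limma adjusted p = 0.0318), the chemokine receptor Ccr7 (-3.34, adjusted p = 0.0474), the transcription factors Irf8 (-1.33) and Tcf4 (-1.31), and Rgs1 (-1.25). The remaining named genes were Rhox8 (-1.14), Snx5 (-1.03), the splicing regulator Mbnl1 (-1.01) and the ribonuclease genes Rnaset2b (-0.92) and Rnaset2a (-0.91), which share near-identical sequence and are uncertain. Fabp6 and Ccr7 were fixed in advance as epithelial and dendritic cell markers, and the epithelial-like and macrophage/monocyte-like shares of the same libraries are given above. A positive log2 fold change was seen for 0 of 6 dendritic cell markers tested (median -0.74) and 1 of 9 epithelial markers (-1.65). The same held for 5 of 12 macrophage/monocyte markers (-0.12) and 1 of 3 B or plasma cell markers (-2.06). Fabp6 was 538 ± 966 CPM (SD, n = 10) in control libraries, a spread larger than its mean, with 2912 in control replicate 4 and 1591 in control replicate 1. Fitted without the low-count filter, its log2 fold change was -5.41 within the dated set and -0.82 within the G1 set. For Ccr7 the larger change was in the G1 set (-1.97 and -4.69). Of the 22 cases with 1 library left out, the call ended in 18 for Rgs1, 15 for Rnaset2b, 13 for Rnaset2a, 10 for Snx5, and 9 each for Rhox8 and Tcf4. It ended in 14 of 20 cases for Ccr7 and 6 of 17 for Fabp6, which in the remaining cases fell below the low-count filter and were not tested. Ccr7 was -2.73 without control replicate 8 and -4.32 without control replicate 7, and its highest levels, 564 and 624 CPM, were in control replicates 9 and 10, of 12 and 11 cells. Fabp6 was -4.24 without aGVHD replicate 11 and -5.48 without control replicate 6.

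The lists moved with these genes: 16 of 24 passed camera at the preset correlation, 14 upward and 2 downward, and 0 passed with an estimated correlation (smallest adjusted p = 0.136). By fry, 15 of 24 passed (smallest adjusted p = 0.00433). S100 alarmins had 6 of 9 members higher (adjusted over the list alone 7), specific granule genes 3 of 5 (3), late maturation genes 3 of 15 (11), interferon response genes 3 of 26 (14, and 1 lower), and chemotaxis receptors 5 of 15 (8, and 1 lower). Ribosomal protein genes had 8 of 19 lower (18 over the list alone) and a median log2 fold change of -0.65. Mitochondrial transcripts, the other downward list, had 0 of 11 lower (8 over the list alone), a median of -0.48, and adjusted p = 3.799e-05 by camera and 0.0334 by fry. Their share of named-gene transcripts averaged 15.3% in control and 10.7% in aGVHD libraries, 15.6% and 8.95% in the dated set and 14.7% and 14.3% in the G1 set. The count of 124 fell to 4 when cells of very high totals or high Kcnq1ot1 were left out, and to 3 over the 18 libraries with at least 20 cells. It was 7 within the dated set and 6 within the G1 set.

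Lcn2-positive cells were set against Lcn2-negative neutrophil-like cells of the same libraries, the population named in the study's title. In the 6 aGVHD libraries with at least 5 cells of each status, 36 of 290 genes differed at limma's adjusted p under 0.05, 18 higher and 18 lower in positive cells. No control library had 5 cells of each status, so this comparison speaks of aGVHD only. Status was called after thinning, so negative cells include cells whose Lcn2 transcripts were removed by it. Positive cells numbered 8, 8 and 24 in aGVHD replicates 1, 3 and 4, against 17, 22 and 40 with Lcn2 before thinning. In aGVHD replicates 6, 7 and 11 they numbered 24, 33 and 7, against 43, 52 and 16. The comparison is thus between cells with and without Lcn2 detected at the thinned depth. Of the positive cells 61 of 104 lay in cluster 9, the granule gene cluster, against 13 of 203 negative cells. Lcn2 and granule genes were among the fixed genes from which the clustering genes were drawn. Part of this overlap may thus be built in. Without cluster 9, 4 libraries had enough cells and 0 of 145 genes passed with limma, with 10 at an unadjusted p under 0.05; S100a8 then had 0.32 (SE 0.28) and S100a9 0.49 (SE 0.22). Higher in positive cells were Ngp, a specific granule protein (log2 fold change 3.74, SE 0.47, limma adjusted p = 5.28e-10), Retnlg (2.49), the collagenase Mmp8 (2.33), the metalloprotease Adam8 (1.98), Fpr1 (1.88), S100a8 (1.76) and S100a9 (1.73). S100a8 was 34095 ± 18436 CPM in positive and 8964 ± 1667 in negative cells (SD, n = 6), and was higher in 6 of 6 libraries. Lactoferrin (Ltf, 2.84) rested on 44 transcripts in positive and 1 in negative cells and was higher in 2 of 6 libraries.

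Lower in Lcn2-positive cells were the C-type lectin receptors Clec4n (-1.92) and Clec7a (-1.45), the interferon-induced chemokine Cxcl10 (-1.83), the adhesion molecule Icam1 (-1.71), the cytokine gene Il1a (-1.50), Ninj1 (-1.48), the pore-forming protein gene Mpeg1 (-1.43) and the chemokine gene Ccl4 (-1.41). Icam1 was 282 ± 201 CPM in positive and 1174 ± 527 in negative cells (SD, n = 6), lower in 6 of 6 libraries. Cxcl10 was 0.02 (limma adjusted p = 0.973) when cells were thinned to 500 transcripts of named genes. Leaving out 1 library ended the call of Ccl4 (aGVHD replicates 3, 7 and 11), Mpeg1 (3, 4 and 11) and Ninj1 (6), and Ccl4 was -0.88 without aGVHD replicate 3 and -2.01 without aGVHD replicate 4. Without cluster 9, Ccl4 was 0.34 (SE 0.55). The count was 17 within the dated set, 3 within the G1 set and 12 without aGVHD replicate 7.

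**Figure D2:**
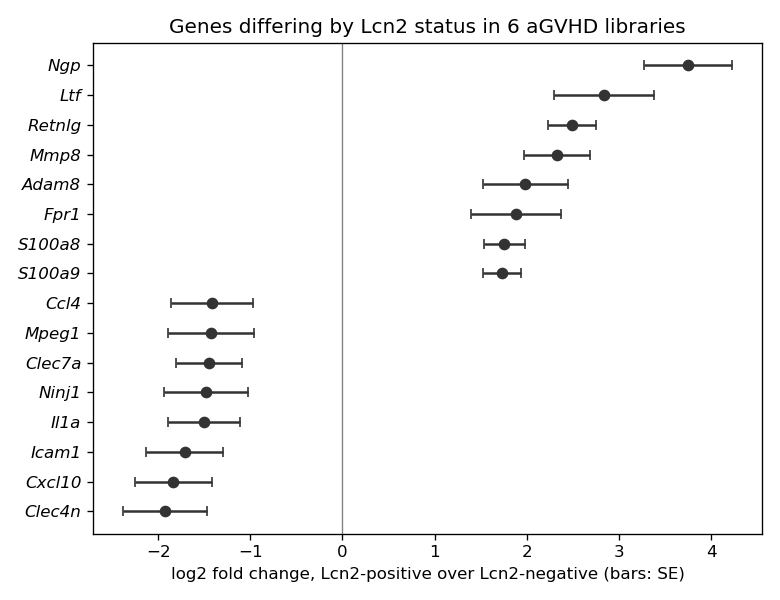
Log2 fold change of the 16 named genes between Lcn2-positive and Lcn2-negative neutrophil-like cells of 6 aGVHD libraries; points are estimates and bars standard errors. Ngp has the highest value at 3.74 and Clec4n the lowest at -1.92.

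Differences between the title sets were tested as interactions. With limma, 0 of 2382 genes over all gated cells and 0 of 1221 in neutrophil-like cells passed, with 121 and 62 at an unadjusted p under 0.05. The interaction of Lcn2 status with group could not be fitted on thinned cells and gave 0 of 1046 genes on unthinned ones, with 60 at an unadjusted p under 0.05.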

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

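All tests in this part were set before their results were seen. Of 24 groups of 4 to 10 libraries checked for a single library far from the rest, 2 were picked out, and chance picks about 1 in 20 groups. Tarm1 over all gated cells was 110.507 CPM in control replicate 3, against 52.0 in the next highest control library. Snx5 was 338.552 CPM in control replicate 9, a library of 12 cells, against 181 in the next highest.

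Transcripts of embryonic globins appeared in barcodes taken to have received no cells, as read from their totals. Hbb-bh1 was at 11247.4 CPM of named genes in the unused barcodes of the aGVHD libraries of the dated set and at 7765 in those of control libraries. Over both groups it was 10123.8 CPM in unused barcodes, against 482 in neutrophil-like cells of the same libraries. That difference is consistent with RNA from other libraries or cells reaching these barcodes. In the G1 set Hbb-y was the more abundant globin, at 7054 (control) and 6888 (aGVHD) CPM in unused barcodes. Some kept cells carried these transcripts as well: cluster 12 (42 cells) was led by Hbb-bh1 and cluster 15 (18 cells) by Hbb-y. Both clusters stayed unnamed, and their cells enter the fits over all gated cells and the totals behind the shares of kept cells. No biological explanation was tested, since no group of the study concerns embryonic tissue.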

How the results depend on the processing

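The planned model for counts and its planned DESeq2 counterpart were not run, and Lcn2 status could not be fitted on thinned cells in control libraries alone. Alternatives chosen after seeing the data were unweighted values, sample weights, named genes only, minimum cell numbers per library, the same libraries with no replicate block, unnamed clusters included, leaving out cluster 9 or control replicate 9, both other clusterings, and leaving out libraries for Lcn2 status. Control libraries of 11 to 60 cells limit the depth. The cause of a change was not tested.

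The count of 124 genes over all gated cells was 7282 without a low-count filter (443 higher, 6839 lower, median log2 fold change -0.75), 4 with the cell quality filter, 7 in the dated set, 6 in the G1 set and 3 over libraries of at least 20 cells. Whether title numbers pair the libraries is not settled, since no label says so. Same-numbered libraries correlated from 0.00 to 0.26 in all cells, where most control libraries correlated better with another number. In 3 neutrophil-like pairs they correlated from 0.06 to 0.35. There each control library correlated best with its own number, a hint from the data only. With title numbers as a replicate block the count was 46, against 7 for the same libraries with no replicate block. Leaving out 1 library gave 41 to 179: 41, 62, 80, 74 and 79 without control replicates 1, 4, 6, 8 and 9, and 78, 80, 80, 77 and 75 without aGVHD replicates 2, 3, 4, 6 and 8. For its named genes and Lcn2, 524 settings gave the outcome of the reported fit (a call, or none for Lcn2), 217 ended a call and 6 added one. Lcn2 passed without a low-count filter (2.98), in the G1 set (3.59), with 4 sums (3.79), the replicate block (3.10; 2.24 without it) and unweighted values (2.87), and without aGVHD replicate 10 (2.59). Spread between libraries is not measured by the fit of 4 sums.

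The count of 1 gene in neutrophil-like cells was 8 without a low-count filter, 3 at 250 transcripts per cell, 0 at 1000, 0 in each title set alone, 14 with 4 sums and 31 with the replicate block (0 without it). It was 0 with unweighted values, libraries of at least 20 cells, resolution 0.5, thinned cells, unnamed clusters included or cluster 9 left out, 2 at resolution 1.5 and 4 when clustering on log values. It ranged from 0 to 2 when 1 library was left out: 2 without control replicate 2, and 0 without control replicates 4, 7 and 8 or aGVHD replicates 2, 4, 6 and 8. Lcn2 passed with 4 sums (2.98) and the replicate block (3.50), and ranged from 1.36 to 2.36 with 1 library left out. The fit of 4 sums does not measure the spread between libraries. Of the gene lists, 0 passed with an estimated correlation, 1 without cluster 9 and 6 with unnamed clusters.

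The Lcn2 share difference of 18.6 points lost its call at 1000 transcripts (12.4), without thinning (20.1), in the dated set (14.4), thinned on named genes (11.4) and over libraries of at least 10 neutrophil-like cells (16.01). Control replicate 9, with 1 neutrophil-like cell, carries 3 of these: without it they were 21.7, 28.9 and, on named genes, 20.7, all past 0.05. The call held over all gated cells (12.2), for at least 2 transcripts (8.34), without cluster 9 (12.1) and with 1 library left out (15.7 to 20.1). The neutrophil-like share difference of 21.5 points lost it in the G1 set (16.4) and over libraries of at least 20 cells (15.4), and kept it with 1 library left out (18.1 to 23.7). The 36 genes by Lcn2 status were 98 without thinning, 67 at 1000 transcripts, 17 in the dated set, 3 in the G1 set, 65 without a low-count filter and 12 to 41 with 1 library left out (12 without aGVHD replicate 7). Without cluster 9 they were 0, over 4 libraries, and Ccl4 reversed to 0.34. Cxcl10 reversed to 0.019 when cells were thinned on named genes.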

Other observations

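Neutrophil-like cells divided into clusters with distinct leading genes. Cluster 4 (107 cells) was led by Cxcl10, Gbp5 and Cxcl9, genes induced by interferon. Cluster 6 (98 cells) was led by the chemokine and cytokine genes Ccl4, Tnf and Ccl3, cluster 10 (80 cells) by the NF-kB feedback genes Tnfaip3, Nfkbiz and Nfkbia, and cluster 1 (186 cells) by Txnip, with Mmp9 and Cxcr4 among its 10 leading genes. Cluster 8 (92 cells) was led by Osm and G0s2. Lcn2 was at 8764 CPM of named genes in cluster 9, the granule gene cluster, at 1349 in cluster 8 and at 421 to 527 in the others. Cluster 9 held 16.3% of aGVHD neutrophil-like cells, with 83.4% of their Lcn2 and 98.7% of their Ngp transcripts, but 15.7% of their Il1b transcripts.

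The first pattern weighed is Lcn2 and specific granule genes in aGVHD neutrophil-like cells, where the share of cells with Lcn2 was higher. The Lcn2 level and the single granule genes did not pass in the fit over 17 libraries. The granule list passed only at the preset correlation. The tests without cluster 9 and those of the share of cells were chosen after seeing the data. RNA from other cells may raise Lcn2 everywhere, but Lcn2 was at 260.199 CPM of named genes in unused aGVHD barcodes, against 2677 in aGVHD neutrophil-like cells. Both values are pooled over libraries, unlike the library means of CPM over all genes given above. In aGVHD libraries of the dated set, 768 unused barcodes held 20 Lcn2 transcripts, against 1787 in 376 neutrophil-like cells. These values argue against bleed between barcodes as the source of the pooled aGVHD level. Replicates 7 and 6 held 1051 and 612 of those 1787 transcripts. The other aGVHD libraries of the dated set held 6 to 61 each, and for them bleed stays open. RNA carried into a well together with a sorted cell is not measured by barcodes taken to hold no cell. That source stays open. For the share of cells with Lcn2, median depth was 2270 and 2310 transcripts, and the difference at 500 transcripts per cell was 18.5549 points (SE 4.92). That argues against a difference in total depth per cell, but it is the reported result and not a separate test. Thinning on totals does not equalise transcripts of named genes, whose medians were 1272 in control and 1413 in aGVHD cells. At 1000 transcripts and at 500 of named genes the difference was 12.4 and 11.4 points and did not pass. Without control replicate 9, which held 1 neutrophil-like cell, these were 21.7 and 20.7 points and passed. Depth in named genes is therefore not settled as a cause. For the Lcn2 level the thinned log2 fold change was 2.14733 with an SE of 1.88, too wide to decide. A small cluster rich in granule transcripts is not the whole cause of the difference in share, which was 12.0922 points (SE 3.07) without cluster 9, but part of it may be. For the level it stays open: without cluster 9 the log2 fold change was 0.938935, with an SE of 0.63, and a bound of 0.855 set by the prediction lies within that error. The disease itself is a candidate explanation that these tests leave open.

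Whether chance can be excluded was asked with other splits of the libraries within title sets. For all gated cells, 1 of 100 splits, the real one, gave as many genes as 124, and the highest other split gave 27. That speaks against chance in the grouping only if the libraries are independent, which no label shows. Every control library also held fewer cells (11 to 60) than any aGVHD library (74 to 95), so the splits cannot separate group from cell number. Chance differences between animals are not addressed, since no library is tied to a mouse. For neutrophil-like cells, 10 of 100 splits gave at least the real count of 1 gene, and the highest other gave 36, so chance is not excluded. A split calling many times the real count may point to a structure of the libraries other than their groups. The median of the other splits was 0. Some libraries of a group differed little: chi-square per degree of freedom was 1.33 between control replicates 5 and 6, and 2.96 between aGVHD replicates 9 and 10. It was 15.3 between aGVHD replicates 1 and 11. Low depth also lowers this value, and control replicates 5 and 6 held 12 and 19 cells. Whether close libraries share a mouse is not labelled, and their effect on the splits was not tested. For Lcn2 status, 1 of 32 swaps within libraries, the real one, gave as many as 36, and the highest other gave 16.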
